A study of Homo sapiens with 36 samples.

How the data were processed

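CUT&Tag libraries came from HUDEP-2 cells in 7 groups of 4 with a peak list each, out of 36 libraries described; the 8 IgG control libraries had no peak list used here. Per the labels, cells infected with lentivirus were sorted for GFP before the assay, the anti-GATA2 antibody was made in-house and the anti-HA antibody was commercial. Groups and replicate numbers were taken from the library titles. The genotype label of GATA2-low empty-vector anti-GATA2 replicate 1 reads wild-type while its title reads GATA2-low, and the title was followed. An IgG title stands beside an anti-HA label in 2 of the unused libraries.

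Per the submitters' processing notes, the tools were FastQC, cutadapt 3.3, Bowtie2 2.2.5, deepTools 3.5.3 and MACS2 2.2.7.1 with genome build hg38; their settings are not given in the sources used here. Peaks were deposited per library, not on pooled libraries, in the narrowPeak layout of 10 columns. The deposited fold enrichment of each peak is a linear ratio of the fragments at the summit to the local background. The deposited p and q of each peak are given as -log10 values, and the lowest deposited -log10 q in any list was 6.00. The deposited score is 10 times the -log10 q. These values per peak are the authors' and were used only to rank or filter peaks within a list and to recover depth. Coordinates are printed 1-based on hg38.

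Of 120964 peaks, 455 were left out (111 on the mitochondrial sequence, 322 on chromosome Y and 22 on unplaced sequences). Sites are the merged intervals of the 120509 kept peaks of all 28 libraries, with an overlap of at least 1 bp, and a library has a site if any of its peaks overlaps it. The 17277 sites had a median width of 402 bp, and 3615 of them came from a single library. A 4 against 4 comparison was tested by an exact two-sided permutation of the libraries (70 labelled splits, smallest p = 0.0286) with Benjamini-Hochberg adjustment over the comparisons of the same antibody and measure, or over the 11 lists within a comparison; peak numbers were tested as log2 of the number plus 1, and ratios are ratios of geometric means on that scale. Sites were tested one by one with Fisher's exact test on libraries with and without a peak, where only a split of 4 of 4 against 0 of 4 can reach p = 0.0286. The adjustment of that test was fixed to run over the sites with a peak in exactly 4 of the 8 libraries of a comparison (241 to 3651 sites), which alone could pass; an adjustment over every site with a peak in any of the 8 (1079 to 16782 sites) was added after the data were seen. Lost sites had a peak in 4 of 4 wild-type and 0 of 4 GATA2-low empty-vector anti-GATA2 libraries. A group's shared sites are those in at least 3 of its 4 libraries. For the overlap per library, the sites of each HA-GATA2 library were set against those with a peak in all, or all but 1, of the other HA-GATA2 libraries. The sites of each HA-T354M library were set against each of these 4 reference sets, and the percents were averaged.

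Gene positions came from a RefSeq gene table of assembly GRCh38.p14, which has no exons and no strand. Planned windows around transcription starts were therefore replaced by windows of 1000 bp around either end of a protein-coding gene, nearest start by nearest gene body, and exon and intron classes by gene end, inside and outside. A gene of a list had a peak when a summit lay in its body or within 10 kb. The planned search for GATA and other motifs needs the genome sequence and was not analysed here. The 11 lists were core GATA2 targets, haematopoietic transcription factors, globin and heme synthesis, red cell membrane and iron uptake, cytokine receptors and signalling, mast cell, basophil and eosinophil, megakaryocyte and platelet, neutrophil and monocyte, lymphocyte, unrelated tissues and housekeeping. The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the first 12 core targets and KLF1, ALAS2, HBG1, HBG2 and HBB where a site lies in their window, up to 4 genes of each other list with the largest difference in the number of libraries, and up to 10 sites per direction with the highest mean percentile by -log10 q; some items the rule covers are not reported here. The 8 empty-vector anti-HA sites, the 2 sites without a wild-type peak in the first comparison and single sites at core genes were singled out after their values were seen.

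The files give no read totals. MACS2 tests a whole number of fragments against a Poisson background, so the fragments and background at each peak were recovered from the deposited fold and -log10 p, with a match within 0.03% for 98.9% to 100% of the peaks of each library. The lowest background of a list, divided by the caller's scaling of that library, then estimates the relative depth. The caller had scaled the HA-GATA2 and HA-T354M anti-GATA2 libraries down, by factors of 0.5 to 0.706, and no other library. In an alternative added after the data were seen, fragments were thinned at random to the lowest background of a comparison and peaks counted above a common -log10 p of 10.5. Peak lists hold only peaks past the caller's threshold, so a site without a peak is not shown to be unoccupied, and a shallower or less enriched library loses weak sites first.

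Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The site test was tested on simulated data for the anti-GATA2 comparison of HA-GATA2 and HA-T354M. Of 200 sites made to differ among 14531, 200 were recovered, with 226 called in that direction and 17 called in the other direction. Each of the other sites had the same chance of a peak in every library, so false calls between lists of unequal length were not tested. With equal occupancy simulated at 2 depths for 8000 sites, the ratio of peak numbers was 1.41 before and 0.999 after thinning. Alternatives covered list length, site definition, overlap, window sizes, sequence names, base pairs covered, a stricter threshold, thinning, the adjustment over every site, the replicate number as a block and leaving out each library in turn. With a library left out, a site needed a peak in all remaining libraries of a group and none of the other, so numbers of sites cannot fall by construction.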

Results

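Occupancy of chromatin by GATA2, a zinc finger transcription factor of blood stem and progenitor cells, was measured by CUT&Tag in HUDEP-2 cells, an immortalized human erythroid progenitor line. In CUT&Tag an antibody tethers a transposase to the chromatin it recognises, and the released fragments are sequenced. Wild-type cells and GATA2-low cells (labelled GATA2+/-) received a lentiviral empty vector. GATA2-low cells also received HA-tagged GATA2 or HA-tagged GATA2 with the zinc finger mutation T354M. An antibody against GATA2 was used on all 4 kinds of cells and an antibody against the HA tag on the 3 kinds of GATA2-low cells. Each of these 7 groups had 4 libraries, so 28 peak lists with 120964 peaks were compared, and 120509 of the peaks lay on chromosomes 1 to 22 and X.

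With anti-GATA2 the wild-type empty-vector libraries held 7625 ± 1247 peaks (SD, n = 4), the GATA2-low empty-vector libraries 2430 ± 842, the HA-GATA2 libraries 10395 ± 2274 and the HA-T354M libraries 4830 ± 1528. With anti-HA the numbers were 4248 ± 1758 for HA-GATA2, 595 ± 166 for HA-T354M and 4 ± 2.16 for the empty vector, which carries no HA tag and gives the background of this antibody. Merging the peaks of all 28 libraries gave 17277 sites. Read totals are unknown, and the depth was estimated from the lowest background of each peak list, with the caller's scaling of a library divided out. The mean of this estimate was 0.265 fragments per window in the wild-type libraries and 0.174 in the GATA2-low empty-vector libraries. It was 0.431 and 0.479 in the HA-GATA2 and HA-T354M anti-GATA2 libraries and 0.403 and 0.374 in the HA-GATA2 and HA-T354M anti-HA libraries. The empty-vector anti-HA lists were too short for an estimate. The labels name no separate cultures behind the replicates, so a p-value measures only the spread between these libraries, which may be technical.

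**Figure D1:**
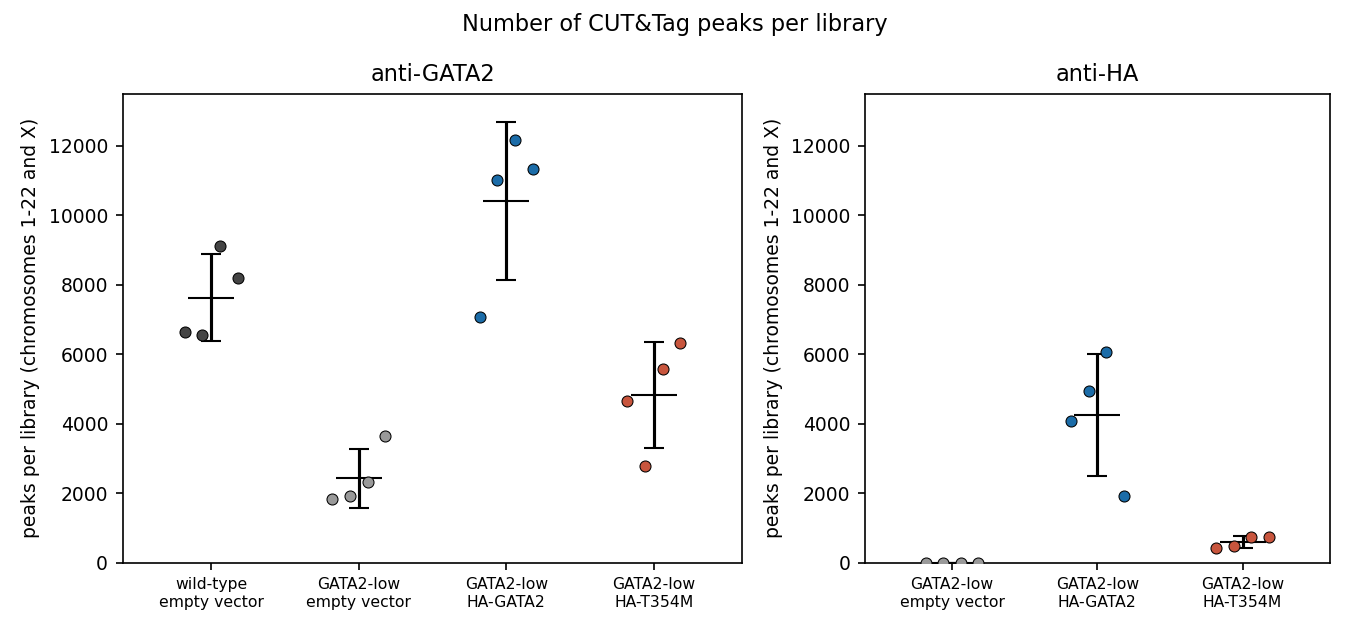
Peaks per library on chromosomes 1 to 22 and X (vertical axis, linear) for the 7 groups with anti-GATA2 on the left and anti-HA on the right; points are libraries, wide ticks are means and bars are 1 SD (n = 4). The HA-GATA2 libraries sit above the HA-T354M libraries with both antibodies, and the empty-vector anti-HA libraries hold 1 to 6 peaks.

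The first comparison asked which chromatin sites depend on a full level of GATA2, by setting wild-type against GATA2-low cells that carried the empty vector. Wild-type libraries held 3.23 times as many anti-GATA2 peaks. At 1524 sites, called lost sites here, a peak was in 4 of 4 wild-type and in 0 of 4 GATA2-low libraries; 2 sites, 149194 bp from MEI4 and inside ZSCAN32, stood the other way. A lost site lay beside TAL1, a partner of GATA factors (chromosome 1, 47238939 to 47239938). Another TAL1 site, from 47231430 to 47232945, held a peak in all 8 libraries. Sites inside ZFPM1, which encodes the GATA cofactor FOG1, stood in both classes. Those at chromosome 16 from 88461141 to 88462573 and from 88512833 to 88513683 were lost sites, and those from 88454468 to 88457176 and from 88491194 to 88492443 held a peak in all 8 libraries. Sites at LYL1, LMO2, GATA1, MYB, KLF1 and ALAS2 also held a peak in every library of both groups.

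Around single genes, the body and 10 kb on either side were searched for peak summits. KIT, the receptor for stem cell factor, had a peak in 3 of 4 wild-type and 0 of 4 GATA2-low libraries. LDB1, the adaptor that links TAL1 and GATA factors, and the transcription factor genes ID2 and TCF4 had a peak in 4 of 4 against 0 of 4, and MYC in 4 of 4 against 1 of 4. The heme synthesis genes UROD and ALAD and the ferritin gene FTL stood at 4 of 4 against 0 of 4 and UROS at 4 of 4 against 1 of 4. Their strongest wild-type peaks had a mean percentile within the lists of 8.42 for FTL, 18.2 for ALAD, 47.4 for UROD and 82.8 for UROS. The peaks at FTL and ALAD were thus weak ones, which a shallower list loses first. Among red cell membrane and iron genes, ADD2, SLC11A2 (an iron transporter) and EPOR (the erythropoietin receptor) stood at 4 of 4 against 1 of 4 and XK at 3 of 4 against 0 of 4. Among cytokine genes, IL6ST stood at 4 of 4 against 0 of 4, CISH at 4 of 4 against 1 of 4, and FLT3 and TGFBR1 at 3 of 4 against 0 of 4. IL1RL1, the mast cell and basophil receptor for interleukin 33, and LTC4S stood at 4 of 4 against 0 of 4, TPSAB1 (a tryptase) at 4 of 4 against 1 of 4 and HPGDS at 3 of 4 against 0 of 4.

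Gene lists fixed beforehand were counted as the number of their genes with a peak per library. The number was higher in wild-type libraries for 8 of the 11 lists (exact permutation adjusted p = 0.0393 each, n = 4 and 4). Among blood genes these were the core GATA2 targets (11.8 ± 0.5 against 9.75 ± 0.5 of 16 genes), the other haematopoietic transcription factors (15.2 ± 1.5 against 6 ± 1.15 of 31) and globin and heme synthesis (13.5 ± 0.577 against 8.25 ± 1.26 of 25). They were also cytokine receptors and signalling (15 ± 2.83 against 5.25 ± 3.3 of 30) and mast cell, basophil and eosinophil genes (9.5 ± 1.29 against 3.25 ± 0.5 of 27). The remaining lists were lymphocyte genes (3.25 ± 0.957 against 0.25 ± 0.5 of 25), genes of unrelated tissues (4 ± 0 against 1.25 ± 0.5 of 26) and housekeeping genes (8.75 ± 1.5 against 0.25 ± 0.5 of 26). The housekeeping genes CHMP2A, YWHAZ, RPL13A and GPI and the unrelated genes GAD2 and SYP stood at 4 of 4 against 0 of 4, so the gain was not limited to blood genes. Red cell membrane and iron genes (29.5 ± 1.91 against 24.5 ± 3.11 of 35) did not pass (exact permutation adjusted p = 0.0943). Megakaryocyte genes (5.25 ± 0.957 against 2.25 ± 1.5 of 26) and neutrophil and monocyte genes (2.75 ± 0.5 against 2 ± 0 of 26) did not pass either (adjusted exact permutation p = 0.0698 and 0.143). As a percent of each library's peaks, 0 of the 11 lists passed in the exact permutation test after adjustment and 5 had an unadjusted p of 0.0286 (adjusted 0.0629). Lymphocyte, unrelated-tissue and housekeeping genes took more of the wild-type peaks, and red cell membrane and iron genes (0.932% against 1.77%) and neutrophil and monocyte genes took less. The core targets (0.639% against 0.931%), haematopoietic transcription factors (0.365% against 0.466%) and globin and heme genes (0.413% against 0.589%) were also a smaller share in wild-type cells (exact permutation p = 0.0571 for each).

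The ratio of 3.23 had an exact permutation p of 0.0286 (two-sided, n = 4 and 4, the smallest this design gives; 0.0429 after Benjamini-Hochberg adjustment over 6 anti-GATA2 comparisons). Fisher's exact test called all 1526 sites when adjusted, as fixed beforehand, over the 1805 sites with a peak in exactly 4 of the 8 libraries (adjusted p = 0.0338). Adjusted over all 11156 sites with a peak in any of the 8, Fisher's exact test called 0 (adjusted p = 0.209; 1526 at an unadjusted p of 0.0286). With that wider adjustment it called 0 sites in every other comparison below too (Fisher's exact test, smallest adjusted p from 0.113 to 0.639). With fragments thinned at random to a common background the ratio was 2.53 with 652 lost sites against 31 the other way, and that ratio, like the ratio without any single wild-type replicate, had an adjusted exact permutation p of 0.0571. Without GATA2-low empty-vector replicate 1, whose genotype label reads wild-type although its title reads GATA2-low, or without replicate 2, 0 lists passed. The same held after thinning, with lists of equal length, with -log10 q of at least 15 and with gene ends alone. Without empty-vector replicate 4, 8 lists passed as a percent of peaks. The 1524 and 2 sites became 65 and 38 with lists of equal length and 1400 and 126 with peaks trimmed around the summit, and the 2 became 5 without empty-vector replicate 2.

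The anti-HA libraries asked where the tagged proteins themselves sat. HA-GATA2 gave 864 times and HA-T354M 128 times as many peaks as the empty vector (exact permutation p = 0.0286 for each, n = 4 and 4). The depth of the empty-vector anti-HA libraries is unknown, so these ratios were not checked against depth. The empty-vector peaks lay on 8 sites, and 4 of these lay at histone genes: H2AC20 at chromosome 1 from 149886464 to 149887145, and H2BC11, H2BC12 and H2BC14 on chromosome 6. All 1753 sites with a peak in 4 of 4 HA-GATA2 and 0 of 4 empty-vector libraries, and all 241 such sites of HA-T354M, were called (Fisher's exact test, adjusted p = 0.0286 for each). HDC, which encodes the histamine-forming enzyme, held the site at chromosome 15 from 50260142 to 50261853 in all 4 libraries of both tagged proteins and in all 16 anti-GATA2 libraries. The same held for sites inside ZFPM2 (chromosome 8, 105520079 to 105521301) and MTSS1 (chromosome 8, 124635080 to 124636495) and at PDZK1IP1 (chromosome 1, 47180225 to 47182847), next to the TAL1 locus.

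With HA-GATA2, 8 of the 11 gene lists had more genes with an anti-HA peak than the empty vector (exact permutation adjusted p = 0.0393 each), in which no listed gene had a peak. Since those libraries hold 1 to 6 peaks, any list with a gene in each HA-GATA2 library reaches the smallest p whatever its genes, and a percent of peaks cannot be compared. The means were 10.8 ± 1.26 core targets, 11.2 ± 4.11 haematopoietic transcription factors, 11.2 ± 3.5 globin and heme genes and 22.2 ± 3.77 red cell membrane and iron genes. They were 9.25 ± 4.99 cytokine genes, 8.5 ± 3.11 mast cell, basophil and eosinophil genes, 2.25 ± 0.957 megakaryocyte genes and 1.5 ± 0.577 neutrophil and monocyte genes. FOXO3, CEBPE, NFE2, KLF1, CPOX, FECH, ALAS2, EPB42, CA1, RHCE, TMCC2, LYN, STAT3, PIM1, MITF and IL1RL1 each had a peak in 4 of 4 HA-GATA2 libraries. Lymphocyte, unrelated-tissue and housekeeping genes did not pass (adjusted exact permutation p = 0.143). Without HA-GATA2 anti-HA replicate 4 the 11 lists all passed, these 3 included, and the 1753 sites became 3308; without any single empty-vector replicate 0 lists passed. With HA-T354M 0 lists passed in the same test and 5 had an unadjusted p below 0.05. CEBPE, FECH, CA1, TMCC2, EPB42, HDC, LYL1 and ZFPM1 had an anti-HA peak in 4 of 4 HA-T354M libraries.

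With anti-GATA2, HA-GATA2 in GATA2-low cells gave 4.36 times as many peaks as the empty vector (exact permutation p = 0.0286, adjusted 0.0429), and 3353 sites had a peak in 4 of 4 HA-GATA2 and 0 of 4 empty-vector libraries, against 0 the other way (Fisher's exact test, adjusted p = 0.0311). Of the 10 such sites with the highest ranks within the HA-GATA2 lists, 4 lay inside ZFPM2, a GATA cofactor gene (chromosome 8, 105568721 to 105569767), inside CNRIP1 (chromosome 2, 68305921 to 68306772), inside ANGPT2 (chromosome 8, 6515999 to 6517578) and 25751 bp from GFI1 (chromosome 1, 92446260 to 92447292). Others of the 10 lay at a further position inside ZFPM2, inside RIPPLY2-CYB5R4 and CPNE3, 10389 bp from CA8 and 8135 bp from MLXIP. The number of genes with a peak was higher in 9 of 11 lists (exact permutation adjusted p = 0.0349 each), with 17.2 ± 2.06 against 8.25 ± 1.26 globin and heme genes, 18 ± 0.816 against 5.25 ± 3.3 cytokine genes and 13.5 ± 3.32 against 3.25 ± 0.5 mast cell, basophil and eosinophil genes. MECOM, SPI1, KIT, FLT3, IL1RL1, CPA3, PRG2 and CCR3 had a peak in 4 of 4 HA-GATA2 and 0 of 4 empty-vector libraries, as did HBG1 and HBG2, which share a site at chromosome 11 from 5244526 to 5244946. Red cell membrane and megakaryocyte genes did not pass (adjusted exact permutation p = 0.0571), and 0 lists passed as a percent of peaks (adjusted exact permutation p = 0.0524 for the 6 with an unadjusted p of 0.0286). By that share the core targets (0.539% against 0.931%), globin and heme genes (0.317% against 0.589%), red cell membrane and iron genes (0.879% against 1.77%) and neutrophil and monocyte genes lay lower with HA-GATA2, and lymphocyte and housekeeping genes higher. The ratio did not pass after thinning (3.65) or with -log10 q of at least 15 (5.11; adjusted exact permutation p = 0.0571 for both), and with lists of equal length or gene ends alone 0 lists passed. The 3353 and 0 sites became 249 and 122 with lists of equal length, 2965 and 145 with peaks trimmed around the summit and 2174 and 16 after thinning. Without HA-GATA2 anti-GATA2 replicate 1 the 3353 sites became 5536. Without empty-vector replicate 1 or 4, 7 and 8 lists passed as a percent of peaks. The lists of these groups were not made alike, since the caller scaled only the HA-GATA2 libraries down. The lowest deposited fold was 2.00 to 2.21 in the HA-GATA2 lists and 1.16 to 1.49 in the empty-vector lists. Mitochondrial peaks numbered 0 in the former and 7 ± 2 in the latter. How far this changed the ratio was not tested.

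HA-T354M gave 1.98 times as many anti-GATA2 peaks as the empty vector, which did not pass (exact permutation p = 0.0571, adjusted 0.0686), and 1.5 times after thinning (adjusted p = 0.2). There were 447 sites with a peak in 4 of 4 HA-T354M and 0 of 4 empty-vector libraries and 3, located 1056410 bp from CNTN5 and inside HPSE2 and FBXO28, the other way; none was called after adjustment by Fisher's exact test (adjusted p = 0.0575), while all 450 had an unadjusted p of 0.0286. They included sites 81327 bp from RREB1, 10389 bp from CA8, inside TPMT and 14516 bp from TNFAIP3. MECOM, KIT, FLT3, TGFBR1, IL1RL1, CPA3 and ALOX5 had a peak in 4 of 4 HA-T354M and 0 of 4 empty-vector libraries, KLF3, ID2, CCR3 and RAG1 in 3 of 4 against 0 of 4. In the exact permutation test 0 lists passed after adjustment and 2 had an unadjusted p below 0.05, the core targets (11.8 ± 0.5 against 9.75 ± 0.5) and the mast cell, basophil and eosinophil genes (9.75 ± 2.5 against 3.25 ± 0.5). The core targets as a percent of peaks lay the other way (0.787% against 0.931%; exact permutation p = 0.171). By that share 0 lists passed and 3 had an unadjusted p of 0.0286 (exact permutation adjusted p = 0.105), red cell membrane and iron genes lower with HA-T354M (1.08% against 1.77%) and lymphocyte and housekeeping genes higher. Without HA-T354M anti-GATA2 replicate 2, the library with the fewest peaks of its group (2779), the 447 sites became 1068, and without empty-vector replicate 4 they became 703. The 3 sites became 9 without empty-vector replicate 1 and 6 without HA-T354M replicate 3, and with lists of equal length the 447 and 3 became 160 and 56. The caller scaled the HA-T354M libraries down as well, and their lists had a lowest fold of 2.03 to 2.15 and 0 mitochondrial peaks.

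How far peaks returned at the 1524 sites lost in GATA2-low cells was measured in the libraries of the tagged proteins, which took no part in choosing the sites. With anti-GATA2, 74.3% ± 10.6 of the lost sites held a peak in HA-GATA2 libraries and 47.3% ± 19.3 in HA-T354M libraries, a difference of 27.0 percentage points that missed the threshold (exact permutation p = 0.0571, n = 4 and 4) and was 17.9 points without HA-T354M replicate 2. With anti-HA the means were 34.3% ± 15.1 and 2.56% ± 1.35, a difference of 31.7 points (exact permutation p = 0.0286, n = 4 and 4). As a background, GATA2-low empty-vector libraries held out of the choice in turn had a peak at 3.05% to 31.7% of the sites, and wild-type libraries held out in the same way at 76.1% to 96.2%. In at least 3 of 4 libraries, 1088 of the lost sites held an anti-GATA2 peak with HA-GATA2 and 598 with HA-T354M. With anti-HA these numbers were 424 and 16. The anti-GATA2 peaks can come from the remaining endogenous protein as well as the tagged one. The empty-vector lists used to choose the sites had a mean depth estimate of 0.174, against 0.431 for HA-GATA2 and 0.479 for HA-T354M with anti-GATA2. The effects of this gap in depth, and of the caller's scaling of the tagged anti-GATA2 libraries alone, on the percent of lost sites were not tested.

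Lost sites with a peak in all 4 libraries of both tagged proteins with anti-GATA2 included the TAL1 site from 47238939 to 47239938, the ZFPM1 site from 88512833 to 88513683, a site inside USP14 (chromosome 18, 201131 to 201794) and a site 10502 bp from LYZL4 (chromosome 3, 42349466 to 42350262). The site 232818 bp from CNTNAP5 (chromosome 2, 123791678 to 123792469) had a peak in 4 of 4 HA-GATA2 and 0 of 4 HA-T354M libraries. A RUNX1 site at chromosome 21 from 34889767 to 34890184 and a TAL1 site from 47224531 to 47225208 had a peak in 1 of 4 HA-T354M libraries, against 1 of 4 and 3 of 4 HA-GATA2 libraries. FTL and RPL13A had no peak in any anti-GATA2 library of either tagged protein. When the HA-GATA2 and HA-T354M lists were shortened to equal numbers of their strongest peaks, the differences were -0.968 points with anti-GATA2 (exact permutation p = 0.171) and -0.0328 with anti-HA (exact permutation p = 0.914). Anti-HA lists of 426 peaks are too short to hold a difference of 31.7 points over 1524 sites, so that value says nothing about binding, and shorter lists leave out weak sites with either antibody.

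**Figure D2:**
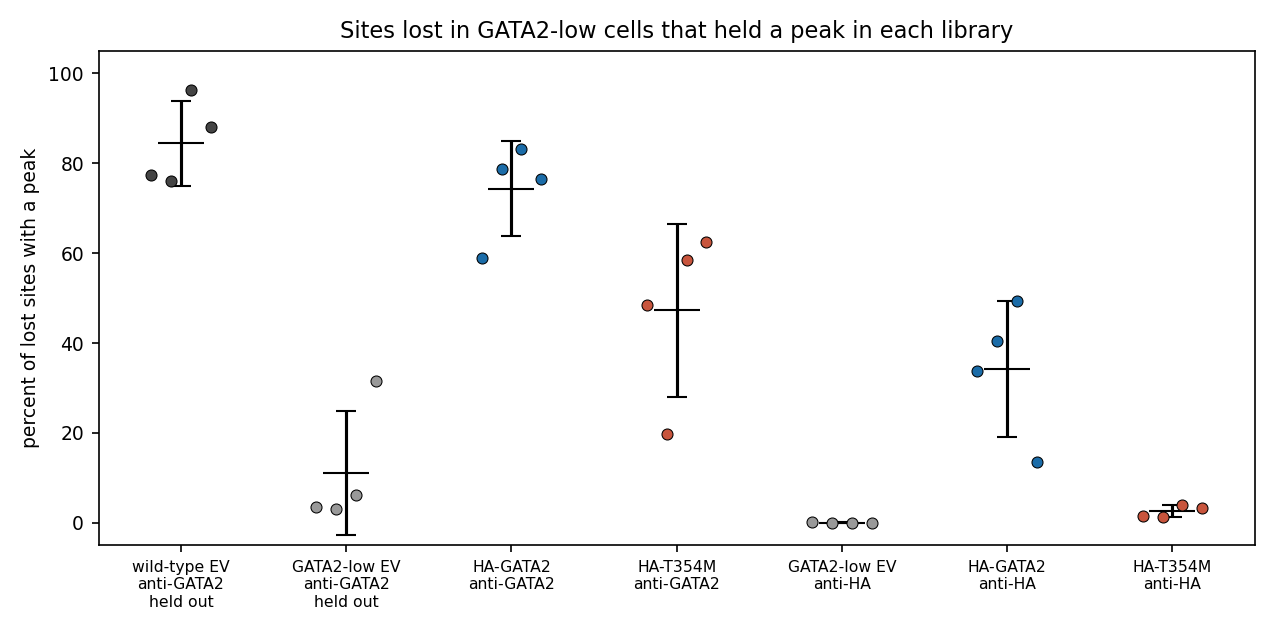
Percent of the 1524 lost sites (vertical axis, linear) that held a peak in each library; points are libraries, wide ticks are means and bars are 1 SD (n = 4), and EV is the empty vector. The held-out groups were measured on sites chosen without the library in question; HA-GATA2 libraries lie between 59.0% and 83.1% with anti-GATA2, and HA-T354M libraries between 19.8% and 62.5%.

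The central comparison set HA-GATA2 against HA-T354M in the same GATA2-low cells, to ask what the zinc finger mutation does to occupancy. HA-GATA2 gave 2.2 times as many peaks with anti-GATA2 and 6.76 times as many with anti-HA. With anti-GATA2, 1484 sites had a peak in 4 of 4 HA-GATA2 and 0 of 4 HA-T354M libraries, and 5 sites the other way; with anti-HA the numbers were 942 and 0. GATA1 held such a site with both antibodies, at chromosome X from 48787708 to 48788425, with a peak in 4 of 4 HA-GATA2 libraries and in no library of any other group. MYB at chromosome 6 from 135195391 to 135195822, the HBG1 site and LMO2 at chromosome 11 from 33881703 to 33882389 stood at 4 of 4 against 0 of 4 with anti-GATA2. With anti-HA these sites held a peak in 0, 2 and 3 of 4 HA-GATA2 libraries, in that order, and in 0 of 4 HA-T354M libraries. Other sites at GATA1, MYB and LMO2 held an anti-GATA2 peak in all 8 libraries.

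The 4 HA-GATA2 sites with the highest ranks and no HA-T354M peak lay 41093 bp from ECI2 (chromosome 6, 4176668 to 4177379), 22207 bp from FZD6 (chromosome 8, 103275504 to 103276287), inside ABLIM1 (chromosome 10, 114661339 to 114662026) and inside TRIM38 (chromosome 6, 25973789 to 25974542). With anti-HA, 4 of the 10 sites with the highest ranks lay inside MDGA1 (chromosome 6, 37666910 to 37668411), 83585 bp from PIK3R1 (chromosome 5, 68385406 to 68386649), inside ESRRG (chromosome 1, 216605997 to 216606914) and at the GFI1 site from 92446260 to 92447292. These 4 sites and those nearest to NOCT, TRHR, CA8 and PRCP and inside ABLIM1 (chromosome 10, 114441985 to 114442761) held anti-GATA2 peaks in 4 of 4 HA-T354M libraries, and the tenth, inside TMEM71, in 3 of 4. The sites at MDGA1, PIK3R1, ESRRG, NOCT, TRHR, CA8 and PRCP also held an anti-GATA2 peak in 4 of 4 GATA2-low empty-vector libraries. Those at GFI1, ABLIM1 and TMEM71 held it in 0 of 4. The 5 sites with an anti-GATA2 peak in 4 of 4 HA-T354M and 0 of 4 HA-GATA2 libraries lay near LTBP2, GOLIM4 and GRAP and inside IGF2R and PAPPA. In wild-type cells those at LTBP2, GOLIM4 and IGF2R held a peak in 4 of 4 libraries, that at GRAP in 3 and that at PAPPA in 2. With anti-HA, HA-GATA2 itself held a peak at GRAP in 4 of 4 and at GOLIM4 in 3 of 4 libraries, and the empty vector held a peak at GRAP in 3 of 4.

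By gene, SPI1 (encoding the myeloid factor PU.1), SPRED1, TGFBR2, SLC11A2, XK, PKLR, SLC18A2, FCGR3A, EBF1, CD4, HBG1 and HBG2 had an anti-GATA2 peak in 4 of 4 HA-GATA2 and 0 of 4 HA-T354M libraries. Their strongest peaks had a mean percentile within the HA-GATA2 lists from 9.66 (FCGR3A) to 59.7 (HBG1 and HBG2). HBE1, ALAS1, ADD2 and SOCS2 stood at 4 of 4 against 1 of 4. GAPDH and TPSG1 stood the other way, at 0 of 4 and 1 of 4 for HA-GATA2 against 3 of 4 for HA-T354M. The core GATA2 targets as a list held 12 ± 0 and 11.8 ± 0.5 genes with a peak (exact permutation adjusted p = 1). No list passed after adjustment; 5 had an unadjusted p of 0.0286 (exact permutation adjusted p = 0.0629). These were globin and heme synthesis (17.2 ± 2.06 against 11 ± 1.63), red cell membrane and iron (30.2 ± 1.26 against 23.5 ± 1.29), cytokine receptors (18 ± 0.816 against 11.8 ± 1.71), lymphocyte (4.75 ± 0.5 against 2 ± 0.816) and neutrophil and monocyte genes (3.25 ± 0.5 against 2 ± 0). The direction turned for 4 of these 5 lists as a percent of peaks, all but lymphocyte genes. Globin and heme genes took 0.317% against 0.419% (exact permutation p = 0.0286, adjusted 0.105). Red cell membrane and iron genes (0.879% against 1.08%), cytokine receptors (0.291% against 0.369%) and neutrophil and monocyte genes (0.0625% against 0.114%) had an exact permutation p of 0.0571 each. The core targets took 0.539% against 0.787% and megakaryocyte genes 0.12% against 0.0347% (exact permutation p = 0.0286 for each), and 0 lists passed, with 3 at an unadjusted p of 0.0286.

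With anti-HA, 6 lists had an unadjusted p of 0.0286 and 0 passed (exact permutation adjusted p = 0.0524). Core targets stood at 10.8 ± 1.26 against 4.5 ± 1, cytokine genes at 9.25 ± 4.99 against 0.25 ± 0.5 and red cell membrane genes at 22.2 ± 3.77 against 7.5 ± 3. As a percent of peaks 0 lists passed and 2 had an unadjusted p of 0.0286 (exact permutation adjusted p = 0.157), the core targets lower with HA-GATA2 (0.778% against 1.72%) and cytokine genes higher (0.275% against 0.0336%). KLF1, TRPS1, STAT5A, FTH1, GYPE, GYPB, EPB41, SLC25A37, LYN, STAT3, PIM1, IL1RL1, PRG2, LMO2 and MYB had an anti-HA peak in 4 of 4 HA-GATA2 and 0 of 4 HA-T354M libraries. Each of them except PRG2, which stood at 3 of 4, had an anti-GATA2 peak in 4 of 4 HA-T354M libraries. Peaks with anti-GATA2 in GATA2-low cells can come from the remaining endogenous protein as well as the tagged one.

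**Figure D3:**
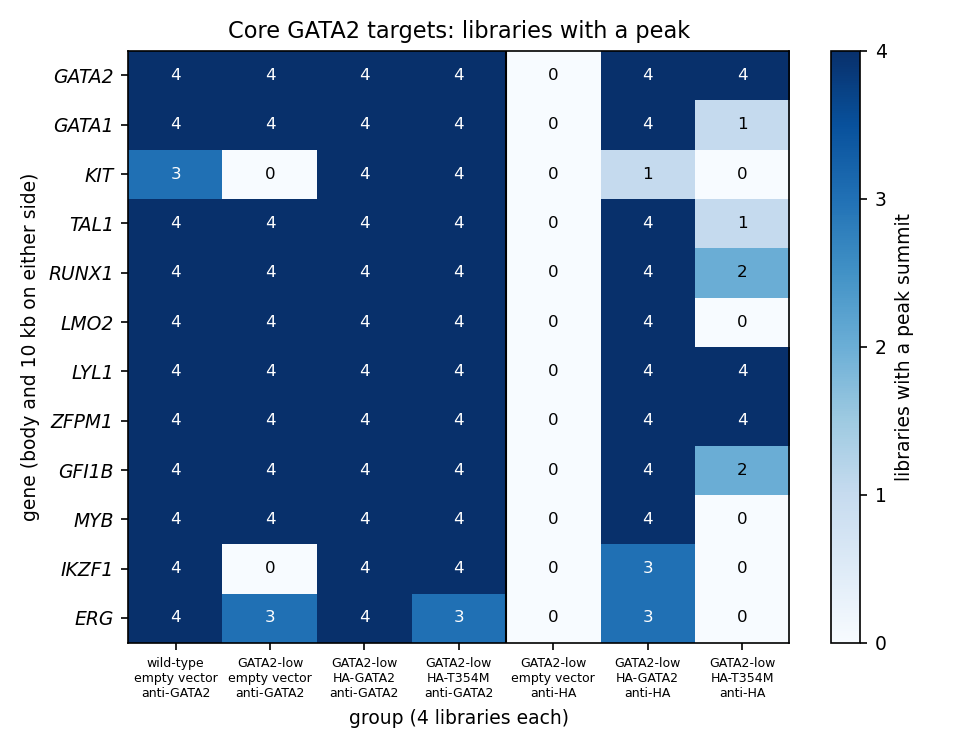
Number of libraries (of 4; colour and digit) with a peak summit in the body of a core GATA2 target or within 10 kb of it, for each gene (vertical) and group (horizontal); HHEX, SAMD14, ETV6 and FLI1, with 0 in every group, are left out. With anti-GATA2 the targets drawn are at 3 or 4 in every group except KIT and IKZF1 in the GATA2-low empty-vector column; with anti-HA HA-T354M is at 4 for GATA2, LYL1 and ZFPM1.

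Most HA-T354M sites were also HA-GATA2 sites. Sites present in at least 3 of 4 libraries numbered 9336 for HA-GATA2 and 4000 for HA-T354M with anti-GATA2, and 3816 were shared, 95.4% of the HA-T354M sites and 40.9% of the HA-GATA2 sites. With anti-HA they numbered 3406 and 402, of which 399 were shared, 99.3% and 11.7%. The 11.7% was 20.6% to 21.3% without HA-GATA2 anti-HA replicate 1, 2 or 3, and 7.55% and 7.49% without HA-T354M anti-HA replicate 3 or 4. With anti-GATA2, 1817 of the 1829 empty-vector sites, chosen by the same rule, were also HA-GATA2 sites. Of the 4000 HA-T354M sites, 3576 were also wild-type sites and 1744 were also empty-vector sites. A high share in the longest list is thus not particular to HA-T354M. Per library, 92.5% ± 4.38 of the sites of HA-T354M libraries were also in at least 2 of 3 HA-GATA2 libraries, averaged over the 4 sets of 3. For the sites of HA-GATA2 libraries, each set against the other 3, this was 85.6% ± 8.85 (exact permutation p = 0.229, n = 4 and 4). With anti-HA these were 96.3% ± 1.35 and 76.7% ± 17.6 (exact permutation p = 0.114). Without HA-GATA2 anti-GATA2 replicate 1 the difference was -11.2 points and without HA-GATA2 anti-HA replicate 4 it was -27.3 points, and both passed (exact permutation p = 0.0286). Without any other single HA-GATA2 replicate it was -16.6 to -14.8 with anti-GATA2 and -34.0 to -30.5 with anti-HA and did not pass. With an HA-GATA2 library left out, the sites used as reference needed a peak in both libraries of a pair, not in 2 of 3. This rule is stricter, so these differences cannot be set against those of the full groups, and the ones that passed say nothing about stability. Within each HA-GATA2 anti-GATA2 list, shared sites had a median percentile of 72.5 to 83 by the authors' -log10 q and sites with no HA-T354M peak 26.8 to 43.9; with anti-HA these were 86.5 to 95.2 and 37.9 to 63.7.

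The peak ratios had an exact permutation p of 0.0286 with each antibody (n = 4 and 4; adjusted 0.0429 with anti-GATA2 and 0.0286 with anti-HA), and the sites were called by Fisher's exact test (adjusted p = 0.039 and 0.0321). Thinned to a common background the ratios were 2.24 (adjusted exact permutation p = 0.0571) and 6.45. The anti-GATA2 ratio did not pass without HA-T354M replicate 1 (2.21) or replicate 2 (1.86; adjusted exact permutation p = 0.0857 and 0.0686). Without HA-GATA2 anti-GATA2 replicate 1 the 1484 sites became 3269 and 8 lists passed, and without HA-GATA2 anti-HA replicate 4 the 942 became 2337 and 9 lists passed. Without HA-T354M anti-GATA2 replicate 2 the 5 sites became 58, and with peaks trimmed around the summit 147. With lists of equal length 159 and 120 sites stood apart in the 2 directions with anti-GATA2, and 32 and 15 with anti-HA.

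Set against wild-type cells, GATA2-low cells with HA-GATA2 had sites of their own and lacked others. There were 1333 sites with a peak in 4 of 4 HA-GATA2 and 0 of 4 wild-type libraries and 202 the other way (Fisher's exact test, adjusted p = 0.0409), although the peak number itself did not pass (1.35 times; exact permutation p = 0.0857). Sites without a wild-type peak included 1 inside MECOM, a stem cell transcription factor gene (chromosome 3, 169510315 to 169510933), 1 inside VPS13B (chromosome 8, 99236385 to 99237236), 1 inside DNAAF10 (chromosome 2, 68133710 to 68134776) and the GATA1 and HBG1 sites named above. SPRED1, TGFBR2, CPA3, SLC18A2, FCGR3A, RAG1 and EBF1 had a peak in 4 of 4 HA-GATA2 and 0 of 4 wild-type libraries. FTL, RPL13A and GPI had a peak in 4 of 4 wild-type and 0 of 4 HA-GATA2 libraries, as did sites inside ROBO2, DCC and IGF2R.

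HA-T354M libraries held 0.612 times as many peaks as wild-type libraries (exact permutation p = 0.0286, adjusted 0.0429). Of the sites, 479 had a peak in 4 of 4 wild-type and 0 of 4 HA-T354M libraries and 53 the other way, with 0 called after adjustment (Fisher's exact test, adjusted p = 0.059) and all 532 at an unadjusted p of 0.0286. The 53 included the MECOM and VPS13B sites, a site 59187 bp from MYB (chromosome 6, 135121429 to 135122121) and 1 inside DOP1B (chromosome 21, 36267754 to 36268380). Haematopoietic transcription factors (11 ± 2.71 against 15.2 ± 1.5 genes) and red cell membrane and iron genes (23.5 ± 1.29 against 29.5 ± 1.91) had an unadjusted p of 0.0286 and 0 lists passed (exact permutation adjusted p = 0.157). As a percent of peaks the direction turned for both, at 0.413% against 0.365% (exact permutation p = 0.0286, adjusted 0.157) and 1.08% against 0.932% (p = 0.171). Mast cell, basophil and eosinophil genes took 0.253% against 0.151% (exact permutation p = 0.0286), and 0 lists passed by that share. HA-GATA2 against wild-type gave 0 lists as well, with 1 at an unadjusted p of 0.0286, globin and heme synthesis (17.2 ± 2.06 against 13.5 ± 0.577 genes; exact permutation adjusted p = 0.236). That list turned round as a percent of peaks (0.317% against 0.413%). By that share 0 lists passed and 4 had an unadjusted p of 0.0286 (exact permutation adjusted p = 0.0786), this list, unrelated-tissue and housekeeping genes lower with HA-GATA2 and mast cell, basophil and eosinophil genes higher. Without any single wild-type replicate, or without HA-T354M anti-GATA2 replicate 1 or 2, the HA-T354M ratio to wild-type did not pass (0.584 to 0.725, adjusted exact permutation p from 0.0571 to 0.0857). That ratio did not pass either after thinning (0.597) or with -log10 q of at least 15. Without HA-GATA2 replicate 1 the 1333 sites became 2669; without wild-type replicate 2 the 202 became 332 and the 479 became 769, which without HA-T354M replicate 4 were 732; without HA-T354M replicate 2 the 53 became 141. With lists of equal length the balance of HA-T354M and wild-type sites turned round, to 146 against 101, and that of HA-GATA2 and wild-type sites became 827 against 490. Mitochondrial peaks, which entered no comparison, numbered 7.25 ± 3.77 in the wild-type and 7 ± 2 in the GATA2-low empty-vector anti-GATA2 lists and 0 in every HA-GATA2 and HA-T354M anti-GATA2 list. This split of the libraries coincides with the comparisons of tagged proteins with wild-type cells and with the empty vector, and HA-GATA2 and HA-T354M lie on the same side of it. The lowest deposited fold parted the same lists, at 1.09 to 1.49 for wild-type and empty vector against 2.00 to 2.21 for HA-GATA2 and HA-T354M.

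The next comparison asked how much of each list lay at the ends of genes. A summit lay within 1000 bp of either end of a protein-coding gene for 23.6% ± 2.06 of wild-type peaks, 11.6% ± 1.52 of GATA2-low empty-vector peaks, 11.6% ± 1.2 of HA-GATA2 peaks and 15% ± 4.52 of HA-T354M peaks with anti-GATA2. With anti-HA the shares were 9.37% ± 2.69 for HA-GATA2 and 11% ± 1.69 for HA-T354M (exact permutation p = 0.429). Of the 1524 lost sites 31.6% lay at gene ends, against 11.6% of the 1298 sites present in all 8 libraries of the same comparison. Gene-end sites made up 48.5% of the 202 sites of wild-type cells without an HA-GATA2 peak and 3.38% of the 1333 HA-GATA2 sites without a wild-type peak. The difference of wild-type lists from each of the other 3 anti-GATA2 groups had an exact permutation p of 0.0286 and an adjusted p of 0.0571, so it did not pass. Without HA-T354M anti-GATA2 replicate 2 the share of HA-T354M lists differed from the empty vector by 5.6 points, and from wild-type by -6.39 points, and HA-GATA2 differed from HA-T354M by -5.59 points (adjusted exact permutation p = 0.0343 each). With lists of equal length the difference from the GATA2-low empty vector turned round, to -1.23 points, and that of HA-GATA2 from wild-type was -13.0 points.

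At the GATA2 locus (chromosome 3, gene body 128479422 to 128493201) a site beyond the gene body from 128495069 to 128496370 held a peak in every library except those of the empty vector with anti-HA. A site inside the gene from 128482702 to 128484003 had an anti-GATA2 peak in 4 of 4 wild-type, 2 of 4 GATA2-low empty-vector, 4 of 4 HA-GATA2 and 4 of 4 HA-T354M libraries, and an anti-HA peak in 2 of 4 HA-GATA2 and 0 of 4 HA-T354M libraries. The site from 128487462 to 128488441 stood at 4, 1, 1 and 3 of 4 libraries with anti-GATA2. A further site inside the gene, from 128485735 to 128487032, had a peak in 1 of 4 wild-type libraries, in 0 of 8 empty-vector GATA2-low libraries and in 15 of the 16 libraries of cells given a tagged protein; it is reported apart because the lentivirus itself carries GATA2 coding sequence, and whether each site is exonic or intronic was not analysed here.

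**Figure D4:**
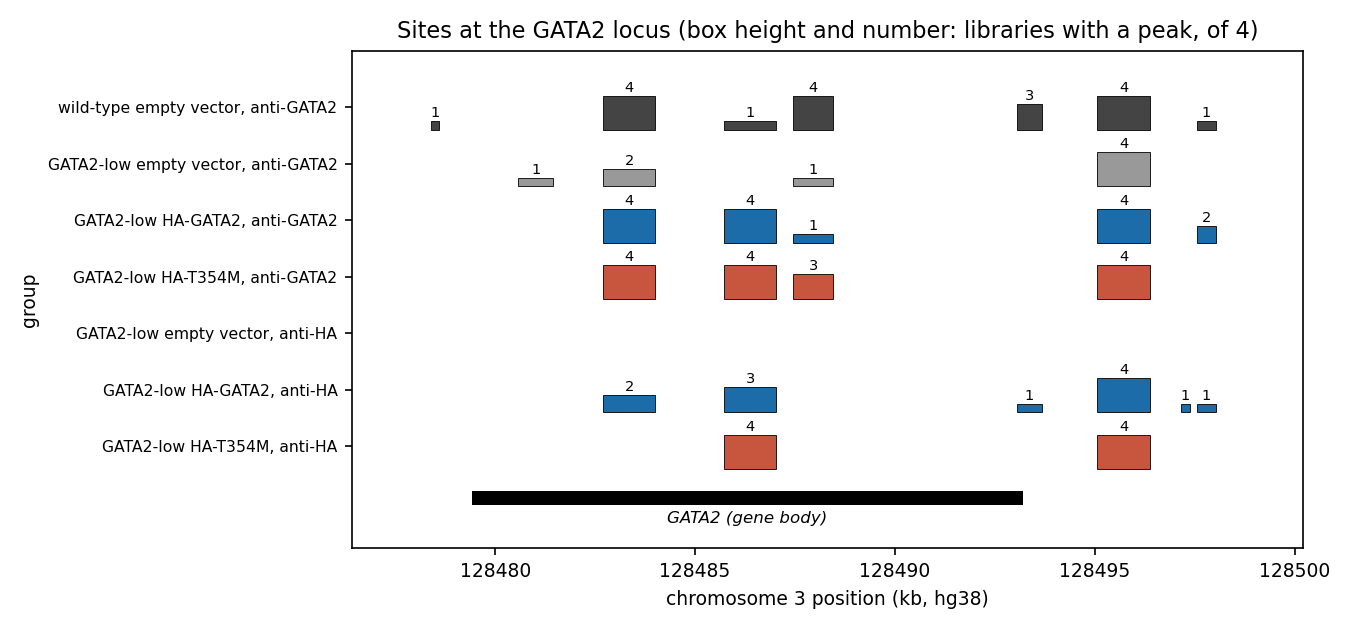
Sites around GATA2 on chromosome 3 (horizontal axis, kb, hg38) in the 7 groups; the height of a box and the digit above it give the number of libraries with a peak (of 4), and the black bar is the gene body. The box from 128485735 to 128487032 stands at 3 or 4 only in cells given a tagged protein.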

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

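The counts over other splits of the libraries and both tests of vector DNA were chosen only after the result was seen. The median peak width of HA-GATA2 anti-HA replicate 4 was 334 bp, while the other 3 libraries of its group lay between 368 and 375 bp. GATA2-low empty-vector anti-GATA2 replicate 4, when held out of the choice of lost sites, had a peak at 31.7% of them, against 3.05% to 6.27% for the other 3 held out in the same way. These 2 libraries were the only ones far from their group by Dixon's test at the 95% level, out of 33 sets of 4 values tested, and chance alone singles out about 1 set in 20. The ratio of HA-GATA2 to HA-T354M peaks was larger with anti-HA (2.76 on the log2 scale) than with anti-GATA2 (1.14), a difference of 1.62 (permutation test over 4900 relabellings, p = 0.00939, adjusted 0.0282). The lists of the antibodies were not made alike, since the caller scaled only the anti-GATA2 libraries of these cells down, by factors of 0.5 to 0.706. Anti-GATA2 peaks can also come from the remaining endogenous protein. The cause of this difference between antibodies was not tested. On the mitochondrial sequence, which the comparisons leave out, HA-GATA2 and HA-T354M anti-HA lists held 5.75 ± 0.5 and 6 ± 0 peaks, against 1.75 ± 2.87 in empty-vector anti-HA lists (exact permutation p = 0.143 for each).

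In each of the 9 comparisons only the real split, 1 of 35, gave so many sites in all 4 libraries of a group and none of the other. That share, 0.0286, is the smallest this design gives. It concerns each total taken alone, not single sites and not the 9 comparisons together. Where the lists of 1 group are longer, a mixed split has long lists on both sides and can hold few such sites. The totals may therefore partly repeat the gap in peak numbers. For HA-T354M against empty vector and against wild-type no single site was called (Fisher's exact test over sites in 4 of 8 libraries, adjusted p = 0.0575 and 0.059; 450 and 532 sites at an unadjusted p of 0.0286). With anti-GATA2 the real total and the highest of the other splits were 1526 and 99 for wild-type against empty vector, 3353 and 201 for HA-GATA2 against empty vector, and 450 and 245 for HA-T354M against empty vector. They were 1489 and 240 for HA-GATA2 against HA-T354M, 1535 and 131 for HA-GATA2 against wild-type and 532 and 84 for HA-T354M against wild-type. With anti-HA they were 1753 and 1 for HA-GATA2 against empty vector, 241 and 0 for HA-T354M against empty vector, and 942 and 53 for HA-GATA2 against HA-T354M. The empty-vector anti-HA lists of 1 to 6 peaks hold every other split near 0, so for both comparisons with them the count of splits decides nothing.

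The first pattern is that HA-T354M gave fewer peaks than HA-GATA2. After thinning the ratios were 2.24 with anti-GATA2 and 6.45 with anti-HA (exact permutation p = 0.0286 for each). These values argue against sequencing depth alone as the cause, although the anti-GATA2 ratio did not pass after adjustment over the comparisons. The same test gave 2.53 for wild-type and 3.65 for HA-GATA2 over the empty vector (exact permutation p = 0.0286 for each). Neither of these passed after adjustment. Depth was left open for HA-T354M over the empty vector at 1.5 (exact permutation p = 0.2). With lists of equal length the sites that stood apart numbered 279 with anti-GATA2 and 47 with anti-HA, 13.9 and 9.4 times the highest other split. They lay in both directions, 159 and 120 with anti-GATA2 and 32 and 15 with anti-HA. The strongest peaks of HA-GATA2 and HA-T354M lists thus differed. Handling, or signal that does not come from the tagged protein, can also change which peaks are strongest. The test therefore cannot exclude a uniform loss of enrichment, as part or as the whole of the cause. The level of each tagged protein and a difference in handling between groups were not tested and stay open beside an effect of the mutation on binding.

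The second pattern is the site inside GATA2 at chromosome 3 from 128485735 to 128487032, seen in 15 of 16 libraries with a tagged protein. DNA of the lentiviral GATA2 insert is a candidate source. Among 2501 sites in all 8 anti-GATA2 lists of these cells, this site lay at the 99.98 percentile for shared interval edges: 7 of 8 lists began at 128485754 and 5 ended at 128487032, against 2 and 2 at the median site. In the 7 anti-HA lists with a peak there, the caller's background at the site lay at or above the 99.53 percentile of the list's peaks, as copies of the insert in the control libraries would make it, but in the 8 anti-GATA2 lists of the same cells it lay at the 52.7 to 89.7 percentile, so that sign is absent there. Binding of the tagged proteins at the endogenous site was not tested apart from the insert and is not excluded.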

How the results depend on the processing

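Thinning to a common background, the threshold of -log10 q of at least 15 and the adjustment of Fisher's exact test over every site with a peak were chosen only after the data were seen. Libraries with the same replicate number showed little likeness between groups (correlations ran from -0.106 to 0.117). The labels do not say whether they were processed together, so pairing stays open and a block by number is given only here. The planned threshold of -log10 q of at least 5 removed 0 peaks and the planned count of repeated intervals met 0 of them, so both say nothing about stability. The motif alternatives were not run. The low depth of the empty-vector lists limits their weak sites. Peak-number ratios kept their direction under every alternative tried, with 88 values on the same side of the threshold and 27 no longer past it. Where no cause is given below, the cause was not tested.

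With the adjustment over every site with a peak, Fisher's exact test called 0 sites in each of the 9 comparisons (smallest adjusted p from 0.113 to 0.639), against 1526, 3353, 1489 and 1535 with anti-GATA2 and 1753, 241 and 942 with anti-HA where it had called any. These sites keep an unadjusted p of 0.0286, and the larger number of tested sites raises the adjusted p by construction.

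Blocked by replicate number the exact sign-flip p was 0.125, the smallest it can give, for wild-type (3.23) and HA-GATA2 (4.36) over empty vector, HA-GATA2 over HA-T354M (2.2), HA-T354M over wild-type (0.612), the anti-HA ratios (864, 128 and 6.76) and the anti-HA return (31.7 points).

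With -log10 q of at least 15 the ratios were 3.34 (wild-type over empty vector), 5.11 (HA-GATA2 over empty vector), 2.46 (HA-GATA2 over HA-T354M; adjusted exact permutation p = 0.0571 for these) and 0.622 (HA-T354M over wild-type; 0.0857). Anti-HA sites over the empty vector became 1126 for HA-GATA2 and 113 for HA-T354M. The lists that passed became 0 for wild-type and for anti-HA HA-GATA2 over the empty vector.

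Thinned, the ratios were 2.53, 3.65, 2.24 (adjusted exact permutation p = 0.0571) and 0.597 (0.0857) in the same order. Sites over the empty vector became 652 for wild-type, 2174 for HA-GATA2 and 210 for HA-T354M, with 31, 16 and 2 the other way, and 0 lists passed for wild-type.

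With lists of equal length, sites over the empty vector became 65 for wild-type, 249 for HA-GATA2 and 160 for HA-T354M, with 38, 122 and 56 the other way. HA-GATA2 sites became 159 against 120 of HA-T354M and 827 against 490 of wild-type, and 32 against 15 of HA-T354M with anti-HA. Wild-type sites without HA-T354M became 101 against 146, which turned the balance round. The anti-HA return turned to -0.0328 points (exact permutation p = 0.914), which lists of 426 peaks fix by construction, and 0 lists passed for wild-type and HA-GATA2 over the empty vector. Shorter lists hold fewer sites by construction. With peaks trimmed around the summit, sites of the empty vector alone became 126 against wild-type, 145 against HA-GATA2 and 12 against HA-T354M, and HA-T354M sites became 147 without HA-GATA2 and 146 without wild-type.

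Counting at least 3 of 4 libraries against 0 of 4 admits more sites by construction: 2716 for wild-type, 5718 for HA-GATA2 and 1156 for HA-T354M over the empty vector, 3408 for HA-GATA2 over HA-T354M, 2759 for HA-GATA2 over wild-type and 1146 for wild-type over HA-T354M. With anti-HA they were 3401 and 397 over the empty vector and 2425 for HA-GATA2 over HA-T354M.

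With gene windows of 50 kb, 8 lists differed in percent of peaks between HA-GATA2 and HA-T354M with anti-GATA2, and 7 in genes with a peak between HA-T354M and the empty vector with anti-HA. With gene ends alone 0 lists passed for wild-type, HA-GATA2 and anti-HA HA-GATA2 over the empty vector.

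Leaving out each library in turn gave ratios of 2.98 to 3.75 (wild-type over empty vector), 0.551 to 0.725 (HA-T354M over wild-type) and 1.86 to 2.49 (HA-GATA2 over HA-T354M). Numbers of sites can only stay or rise when a library is left out, so their ranges below do not measure stability. The shared percents then asked for a peak in every remaining library of the shortened group. Sites ranged from 3383 to 5536 (HA-GATA2 over empty vector; highest without HA-GATA2 replicate 1, as for the next 2), 1486 to 3269 (over HA-T354M) and 1349 to 2669 (over wild-type). They ranged from 452 to 1068 (HA-T354M over empty vector; highest without HA-T354M replicate 2) and 479 to 769 (wild-type over HA-T354M; highest without wild-type replicate 2). With anti-HA they ranged from 1753 to 3308 (HA-GATA2 over empty vector) and 947 to 2337 (over HA-T354M), both highest without HA-GATA2 replicate 4, and the return from 26.7 to 38.6 points (17.9 to 32.1 with anti-GATA2). The shared percent ranged from 90.2 to 99.2 of HA-T354M and 27.3 to 54.4 of HA-GATA2 sites with anti-GATA2, and from 93.3 to 99.6 and 7.49 to 21.3 with anti-HA. The overlap per library ranged from -16.6 to -4.76 points with anti-GATA2 and -34.0 to -19.1 with anti-HA, and passed (exact permutation p = 0.0286) without HA-GATA2 replicate 1 and without HA-GATA2 anti-HA replicate 4. Leaving out an HA-GATA2 library made the rule for its reference sites stricter, so those values do not measure stability. Gene-end shares ranged from 2.32 to 5.6 points (HA-T354M less empty vector), -5.59 to -2.31 (HA-GATA2 less HA-T354M) and -9.67 to -6.39 (HA-T354M less wild-type), passing without HA-T354M replicate 2.

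The lists that passed ranged from 0 to 10 for wild-type over empty vector (0 without empty-vector replicate 1 or 2), 0 to 8 for HA-GATA2 over HA-T354M (8 without HA-GATA2 replicate 1) and, with anti-HA, 0 to 11 for HA-GATA2 over empty vector (0 without any single empty-vector replicate) and 0 to 9 for HA-GATA2 over HA-T354M (9 without HA-GATA2 replicate 4). As a percent of peaks they ranged from 0 to 8 for wild-type and 0 to 8 for HA-GATA2 over empty vector (8 without empty-vector replicate 4).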

Other observations

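The test of clustered sites in ROBO2 was chosen only after the result was seen. The sites held by the tagged proteins with anti-HA differed in how far GATA2-low cells already occupied them. Of the 402 sites in at least 3 of 4 HA-T354M anti-HA libraries, 340 (84.6%) were also in at least 3 of 4 GATA2-low empty-vector anti-GATA2 libraries and 395 (98.3%) in at least 3 of 4 wild-type libraries. Of the 3406 HA-GATA2 anti-HA sites, 1479 (43.4%) were in the GATA2-low empty-vector libraries and 2748 (80.7%) in the wild-type libraries, and 2544 (74.7%) were in the HA-T354M anti-GATA2 libraries. Examples of HA-T354M anti-HA sites that also held a peak in 4 of 4 GATA2-low empty-vector libraries lay inside SMCO1 (chromosome 3, 196511749 to 196512726) and C21orf58 (chromosome 21, 46320049 to 46321221) and 1432 bp from PRKAB1 (chromosome 12, 119664636 to 119666520). These shares come from lists of very different length and were not tested against each other.

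The third pattern is that lost sites at gene ends regained a peak less often than lost sites elsewhere. With HA-GATA2 and anti-GATA2, 59.8% ± 13.7 of the 481 gene-end sites and 81.0% ± 9.4 of the 1043 other sites held a peak, a difference of 21.2 points seen in 4 of 4 libraries (exact sign-flip p = 0.125, the smallest 4 libraries can give). With HA-T354M the difference was 11.1 points. Gene-end sites were also weaker in wild-type cells (median rank 33.3 against 48.9), and within 4 classes of that rank the HA-GATA2 difference averaged 10.2 ± 4.51 points, so weaker peaks may account for part of it and cannot be told apart from the rest; the HA-T354M difference was 1.68 ± 8.55 and is left undecided. A difference in handling of the wild-type and tagged libraries stays open and was not tested.

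A hypothesis was that sites with a peak in 4 of 4 wild-type libraries and in no GATA2-low library of any kind cluster, as a difference in DNA between the wild-type and GATA2-low cells at a single region might make them. ROBO2 (chromosome 3, 75906675 to 77649964) held 5 sites, 3 of them with a peak in 4 of 4 wild-type libraries and none with a peak in any GATA2-low library. Of 1000 random draws of 71 sites from the 4806 present in 4 of 4 wild-type libraries, the median draw had at most 2 sites within 1 Mb and the share with at least 3 gave p = 0.0939 (permutation test), so the test does not decide.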
